A study of Drosophila melanogaster with 17 samples.

How the data were processed

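The series measured where RNA polymerase II and the single-stranded DNA binding protein Rpa70 sat on the genome of Drosophila melanogaster embryos, by chromatin immunoprecipitation and sequencing (ChIP-seq). Per the labels, each sample held 150 hand-picked embryos at nuclear cycle 12 or 13 (NC12, NC13) or 100 embryos from the early, middle or late part of nuclear cycle 14 (NC14E, NC14M, NC14L). The antibodies were against polymerase II phosphorylated on serine 5 of its tail (pSer5), a mark of polymerase that has started transcription, or against the EGFP tag of Rpa70. Processed files of 9 of the 17 samples were used, and the input and control IgG samples, 8 in all, were not analysed here.

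Each deposited file held a coverage signal in windows of 25 bp along genome build dm3, averaged by the authors over 2 replicates per group. The submitters' processing notes name Bowtie, SAMtools and dm3, and the versions, filters and parameters were not given in the sources used here. Every value was a sum of whole multiples of 2 fixed steps, 1 step per replicate, so each file could be separated back into its replicates. At a tolerance of 1e-06, 100% of the windows had such a solution in every file, and at most 0.028% of the windows of any file had another one. The same step recovered 100% of 200000 simulated windows. The steps also gave the number of reads and the read length. The deposited NC12 signal carried an extra common factor of 0.249 and the NC14E signal one of 1.028, which were removed by scaling each replicate to its own total. The read length recovered for mei-41 was 100 bp where the labels give 141 bp. For Rpa70 it was 47 bp, or 57 bp in the zld run 2, where the labels give 67 bp.

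Recovered depth was 16.7 and 11.9 M reads for NC12, 33.3 and 19.8 for WT NC13, 19.0 and 15.5 for NC14E, 15.7 and 12.5 for NC14M, and 18.2 and 14.9 for NC14L. It was 40.7 and 39.9 M reads for mei-41, 38.3 and 35.9 for zld, 33.3 and 19.9 for Rpa70 in WT, and 38.3 and 31.2 for Rpa70 in zld. The matched pSer5 and Rpa70 components at NC13 thus had nearly equal totals in WT, and so did the first ones in zld, for a reason that is not known; levels do not depend on these totals. Reads were not identified by molecule, so counting error understates the error of any level. The components of each file were compared by a chi-square over 1 kb bins. The mei-41 pair and the zld Rpa70 pair differed by about the sampling noise, at 0.96 and 1.21 per bin, where the other 7 pairs had 5.71 to 27.6. Each of these 2 pairs was therefore counted as 1 library, with the levels of its components averaged and the components called runs, which left 16 libraries.

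Levels are reads per kb per M reads of the library. Coordinates are 1-based on dm3. The gene table at hand was of another build and was not used for coordinates or names, so regions carry no gene names and the 25 gene lists set beforehand were not tested. The rule set for this case was applied instead. Bins of 1 kb on 2L, 2R, 3L, 3R, 4 and X, 120384 in all, were engaged in a group when the mean level was above 8 times the median bin. Engaged bins of the 7 pSer5 groups, merged over gaps of up to 1 kb, gave 3908 regions covering 20.4% of the bins, with a median width of 3 kb. The median bin stands for the background of a library. Regions were assigned to the earliest WT stage at which every replicate was above 8 median bins, here called the onset. Regions engaged only in a mutant or in 1 replicate had no onset.

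Ratios are log2 of level plus a pseudocount of about 1 median bin, 1.50 for the WT stages, 1.98 for mei-41, 1.54 for zld and 5.49 for Rpa70, and such ratios understate changes of low regions. Groups were compared with limma 3.58.1 (moderated variance with a trend, Benjamini-Hochberg adjustment over 3908 regions). The 5 WT stages shared a fit with 5 residual degrees of freedom, zld had 2, and mei-41 and Rpa70 had 1 each, from the WT libraries alone. The design foresaw no test for pooled files and a limma test for separate replicates, and the second was used once the replicates had been recovered. A region was called higher or lower when its adjusted p was under 0.05, its log2 ratio was at least 1 in size and its level in the higher group was above 8 median bins. The named regions were, per comparison and direction, the 10 called regions with the most extreme ratios. A region outside this rule is said to have been chosen after its values were seen. These definitions, the calling rule and most of the alternative settings were set before the data were examined. Nothing in the labels says that replicates came from separate collections, so p-values measure only the spread between these libraries, which may be technical. For Rpa70 the prior degrees of freedom came out as infinite. Each region was then tested on a spread pooled over regions of like level, and its own spread had no weight.

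On simulated data with 100 regions changed 4-fold and 100 changed 2-fold, the test called 97, 100, 99 and 100 of the 4-fold regions for the steps from NC12 to NC13, NC13 to NC14E, NC14E to NC14M and NC14M to NC14L. It called 96 for NC14L against NC12, 100 for mei-41 and 100 for zld. Of the 2-fold regions it called 31, 32, 33, 38, 22, 36 and 35 in the same order, with 3, 0, 0, 0, 2, 0 and 0 false calls. For Rpa70 it called 4 of the 4-fold regions and 0 of the 2-fold regions, with 0 false calls, although 100 of each had an adjusted p under 0.05. Few regions had an Rpa70 level above 8 median bins, so the level rule limits that comparison. The simulation gave all libraries of a comparison the spread of its reference group. That was 0.156 in log2 for NC14E over NC13, mei-41 and zld, while the NC14E libraries had 0.257. Beyond read counting and this spread it held no difference between libraries, such as in enrichment. The counts describe that setting and may not hold for the real libraries.

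Median Rpa70 ratios of region lists were set against 10000 random lists of the same size, matched on WT Rpa70 level in 20 bins. The relation of Rpa70 to pSer5 was given as Spearman's rho across regions, which are not independent replicates. The sharpness of a region was the log2 ratio of its 400 bp summit to the mean of the 1 kb on either side. Alternatives changed the pseudocount, scaling, thresholds, bin and gap rules and the summit, left out each replicate in turn, and added other fits chosen after seeing the data. Contigs off the 6 main arms gave no bins or regions. Their reads still counted in the total that scaled each library, except where the total was taken over the main arms. Scripts ran on Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and on R 4.3.3.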

Results

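Engaged RNA polymerase II was followed through the mid-blastula transition of Drosophila embryos, the hours in which the zygotic genome takes over from maternal products. Wild-type (WT) embryos carrying tagged Rpa70 were sampled at NC12, NC13, NC14E, NC14M and NC14L with 2 libraries each, 11.9 to 33.3 M reads deep. At NC13 they were set beside embryos from zld mothers (2 libraries) and mei-41 mothers (1 library). Zelda, the product of zld, is a transcription factor that opens early zygotic promoters and enhancers, and mei-41 encodes the fly homologue of the checkpoint kinase ATR, which slows the cell cycle when replication stalls. Rpa70, the large subunit of the protein that coats single-stranded DNA at stalled forks, was mapped at NC13 in WT (2 libraries) and zld (1 library). The 2 components of the mei-41 sample, and the 2 of the zld Rpa70 sample, differed by about the sampling noise and each pair was counted as 1 sample.

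The part of the genome with engaged polymerase grew over the WT stages, with a lower count at NC14E. At NC12, 6139 of 120384 bins (5.10%) lay above 8 median bins, against 12679 (10.5%) at NC13, 9823 (8.16%) at NC14E, 17205 (14.3%) at NC14M and 19096 (15.9%) at NC14L. The mei-41 library had 3089 engaged bins (2.57%) and zld had 9633 (8.0%), over median bins of 2.61 and 1.67 against 1.31 in WT NC13, so the bar was higher in mei-41. The NC12 libraries differed most, with 5485 engaged bins in replicate 1 and 10581 in replicate 2. At NC14E the drop rested on replicate 2, with 7943 engaged bins over a median bin of 2.22, as replicate 1 had 11956 over a median bin of 1.49 and the NC13 libraries had 11523 and 13362. Of the 3908 regions, 738 were engaged in both libraries at NC12, 1940 at NC13, 1001 at NC14E, 2417 at NC14M and 2837 at NC14L, against 323 in mei-41 and 1556 in zld. Of the NC12 regions, 621 (84.1%) were still engaged at NC13, and 965 (49.7%) of the NC13 regions were engaged at NC14E. By onset, 738 regions belonged to NC12, 1319 to NC13, 33 to NC14E, 796 to NC14M and 478 to NC14L, and 544 had no WT onset.

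**Figure D1:**
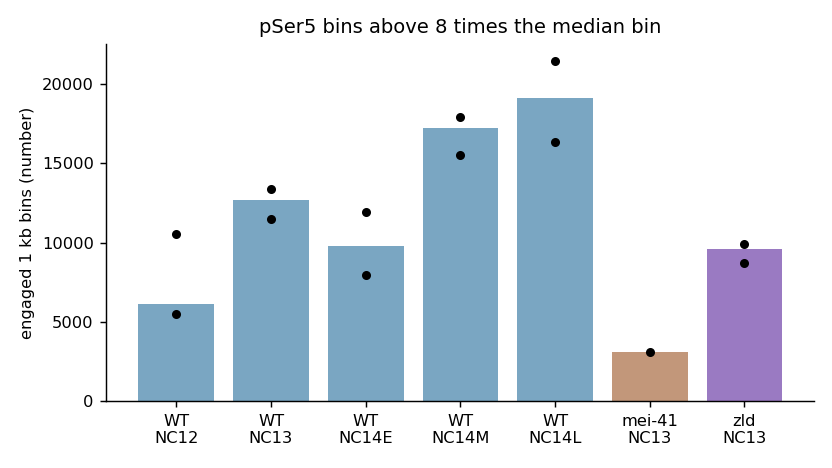
Number of 1 kb bins with a pSer5 level above 8 times the median bin (y axis) in each group (x axis); bars count bins by the mean of the libraries and points count them in each library. WT bars run from 6139 at NC12 to 19096 at NC14L, and mei-41 (1 library) has the lowest bar, 3089.

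From NC12 to NC13 the pSer5 level was higher at many regions, while a smaller set fell. In the comparison of the first wave of zygotic transcription with the next cycle, 859 regions were higher at NC13 and 119 were lower. Of the 1319 regions with an NC13 onset, 741 (56.2%) were called higher, which follows in part from how onset was defined. On chromosome 4, 22 of 65 regions (33.8%) were higher and 1 lower, and on the other arms 19.9% to 23.6% were higher, a difference that was not tested. A 7 kb region on 2R (start 8684001, end 8691000) rose from 7.38 ± 1.47 (SD, n = 2) to 54.7 ± 5.99, a log2 ratio of 2.67 with a standard error of 0.30 (adjusted p from limma 0.00025). The 1 kb region on 2L (start 431001, end 432000) rose from 5.42 ± 2.25 to 42.5 ± 4.42 (log2 2.70). Another, on 2R (start 3074001, end 3075000), had the highest ratio, 3.47, but one that moved between 2.77 without NC12 replicate 1 and 4.12 without NC12 replicate 2. Among the regions that fell, 3R (start 26437001, end 26445000) dropped from 49.1 ± 12.1 to 6.47 ± 1.05 (log2 -2.65), and 3L (start 4480001, end 4482000) from 46.9 ± 3.34 to 5.54 ± 1.17 (log2 -2.79). The region on 3R (start 4103001, end 4106000) was still at 59.2 ± 7.11 at NC13 after 269 ± 42.9 at NC12. The lowest ratio, -3.07, was on X (start 2684001, end 2688000), where the 2 NC12 libraries read 70.9 and 265 and the 2 NC13 libraries 5.08 and 40.1. It lost its call without NC12 replicate 2 (-2.12) or without NC13 replicate 1 (-1.74).

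In this step the median of all regions moved by 0.81, but that of the NC12 class by -0.06 and that of the NC13 class by 1.10. A scaling that set regions engaged at both stages to a median of 0 lowered that median by 0.19 and gave 597 higher and 165 lower. With the 2 NC12 libraries correlating at only 0.65 over bins (log2 levels), against 0.94 at NC13, levels at NC12 are the least certain. The NC12 libraries also held reads in only 28.4% and 19.4% of the 25 bp windows, against 57.7% and 49.5% at NC13. How far this difference between libraries adds to the count of higher regions was not tested.

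The entry into NC14 was marked by loss at early regions more than by gain. Of the called regions, 128 were lower at NC14E than at NC13 and 25 were higher, and 94 of the 128 had been engaged since NC12. The median of the 738 NC12 regions was -0.39, against 0.03 for the NC13 regions. On 3L (start 1638001, end 1655000) the level fell from 142 ± 9.95 to 22.3 ± 7.75 (log2 -2.63 with a standard error of 0.21, limma adjusted p 0.0011). On 2L (start 5538001, end 5556000) it fell from 260 ± 28.9 to 49.0 ± 13.7 (log2 -2.39), and on 2R (start 281001, end 293000) from 24.4 ± 2.54 to 4.15 ± 1.05 (log2 -2.20). The region on 3L (start 10319001, end 10334000) ended at 3.84 ± 0.15 after 26.6 ± 3.12. Among the regions that rose, 3L (start 18996001, end 19039000) spans 43 kb and went from 10.7 ± 0.65 to 32.0 ± 1.93 (log2 1.45), and X (start 8108001, end 8138000) spans 30 kb and went from 11.9 ± 0.55 to 32.9 ± 3.0 (log2 1.36). On 2L (start 16260001, end 16292000) a 32 kb region rose from 6.04 ± 0.57 to 18.5 ± 0.33.

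Gains at NC14E depended on scaling. Dividing each library by its own background shifted the median region by -0.37 and left 1 region higher and 130 lower, 0.80% of calls higher where the scaling by total reads gave 16.3%. Counts also hung on single libraries: 11 higher and 30 lower without NC13 replicate 1, 7 and 23 without NC13 replicate 2, and 23 and 68 without NC14E replicate 2.

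Between NC14E and NC14M polymerase rose again at more regions than it fell. There 174 regions were higher and 27 lower, and 124 of the 174 belonged to the 796 NC14M regions, as follows in part from the definition of onset. On X (start 3267001, end 3284000) the level rose from 5.55 ± 1.38 to 22.1 ± 0.25 (log2 1.76 with a standard error of 0.20, limma adjusted p 0.012). On 2R (start 11878001, end 11882000) it rose from 4.06 ± 0.84 to 16.8 ± 2.19, and on 3L (start 5624001, end 5644000) from 7.75 ± 3.45 to 28.2 ± 1.78. Of the 27 lower regions 25 had an NC12 onset. Among them 3L (start 13824001, end 13835000) fell from 61.9 ± 24.5 to 8.85 ± 1.55 (log2 -2.57) and 3R (start 459001, end 472000) from 221 ± 12.4 to 66.7 ± 5.38 (log2 -1.71). The region on X (start 2139001, end 2146000) met the calling rule at an adjusted p of 0.05 and lost its call whichever of the 8 libraries of NC13 to NC14L was left out.

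The count of higher regions was fragile. It was 1 without NC14E replicate 1, 1 without NC14M replicate 1 and 1 without NC14M replicate 2, with 3, 2 and 4 lower, and without NC14E replicate 2 the lower count was 50. Dividing by background gave 361 higher and 4 lower (98.9% of calls higher, against 86.6% for total reads, with the median shifted by 0.30), and setting shared regions to 0 gave 13 and 56 (18.8%, shift -0.36); taking the total over the main arms gave 120 and 33 (78.4%).

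The last step, from NC14M to NC14L, brought new regions and deep losses at several early ones. Here 94 regions were higher and 48 lower. On X 3 regions within 11 kb, starting at 12195001, 12199001 and 12205001 and each 1 kb long, went from 0.50 ± 0.25, 0.70 ± 0.99 and 0.80 ± 0.59 to 11.9 ± 2.48, 15.7 ± 1.32 and 12.5 ± 3.21. On 3R the regions starting at 3975001, 3981001 and 3986001 reached 12.3 ± 1.02, 13.0 ± 1.12 and 14.9 ± 2.79 from 1.41 ± 0.95, 1.82 ± 0.46 and 2.01 ± 0.67. Of these 6 regions all but those starting at 12199001 and 3981001 lost their call in at least 1 fit that left out an NC14M or NC14L library. On 3L (start 4223001, end 4228000) the level went from 15.3 ± 1.59 to 69.4 ± 11.1 (log2 2.07 with a standard error of 0.15, limma adjusted p 0.00064). Of the 48 lower regions 46 had an NC12 onset. The deepest fall was on 2L (start 6367001, end 6379000), from 558 ± 76.7 to 26.3 ± 20.5 (log2 -4.55, or -5.39 without NC14L replicate 1 and -3.72 without NC14L replicate 2). On 3R (start 27010001, end 27023000) the level fell from 97.1 ± 1.35 to 9.48 ± 0.91 (log2 -3.17).

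This split too moved with scaling: 25 higher and 7 lower after division by background (78.1% higher, against 66.2% for total reads), and 42 and 64 with shared regions at 0 (39.6%, median shift -0.21). It moved with single libraries as well, to 20 higher and 36 lower without NC14M replicate 1, 25 and 33 without NC14M replicate 2, 25 and 39 without NC14L replicate 1, and 8 and 28 without NC14L replicate 2. The spread is shared across stages, so the higher count also became 53 without either NC13 library, 161 without NC12 replicate 1 and 162 without NC12 replicate 2.

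Over the whole course, many early regions lost polymerase as later ones came on. Against NC12, 2487 regions were higher at NC14L and 428 lower (limma), with 342 of the 738 NC12 regions lower and 92 higher. Of the 796 NC14M regions 747 were higher and 0 lower (limma), which follows in part from how onset was defined. The strongest loss was on 2L (start 4679001, end 4691000), with 881 ± 120 at NC12, 768 ± 82.4 at NC13, 165 ± 136 at NC14E, 14.9 ± 10.8 at NC14M and 1.12 ± 0.16 at NC14L, near the median bin of 1.41 (log2 -8.39, adjusted p 5.8e-06). On 2L (start 19697001, end 19704000) the level went from 729 ± 40.7 to 2.93 ± 1.30 (log2 -7.39), with 263 ± 20.8 already at NC13. Losses differed in timing. The 2L region starting at 6367001 held 953 ± 51.9 at NC12 and 964 ± 13.2 at NC14E before it dropped, while X (start 19984001, end 19987000) went from 171 ± 0.76 at NC12 to 75.5 ± 2.0 at NC13 and 16.3 ± 8.65 at NC14E. Of the regions that came on, X (start 15448001, end 15449000) had no reads at NC12 and reached 46.1 ± 3.48 at NC14L, at least 214-fold higher against a floor of 3 reads per library. On 3L (start 19628001, end 19629000) the rise against this floor was at least 118-fold, to 25.4 ± 7.78. These folds are no firm lower bounds, as the floor lies below the NC12 median bins of 1.85 and 1.00. Only 28.4% and 19.4% of the 25 bp windows held reads in the NC12 libraries, fewer than in any other library. On 3L (start 271001, end 273000) the level climbed at each stage, from 0.91 ± 1.29 over 6.06 ± 0.80, 12.1 ± 4.70 and 35.1 ± 5.04 to 59.6 ± 12.1 (log2 4.76, or 5.41 without NC12 replicate 1 and 4.15 without NC12 replicate 2). The median of all regions rose by 1.70, by 0.39 less with shared regions at 0, and 2204 were then higher and 501 lower.

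**Figure D2:**
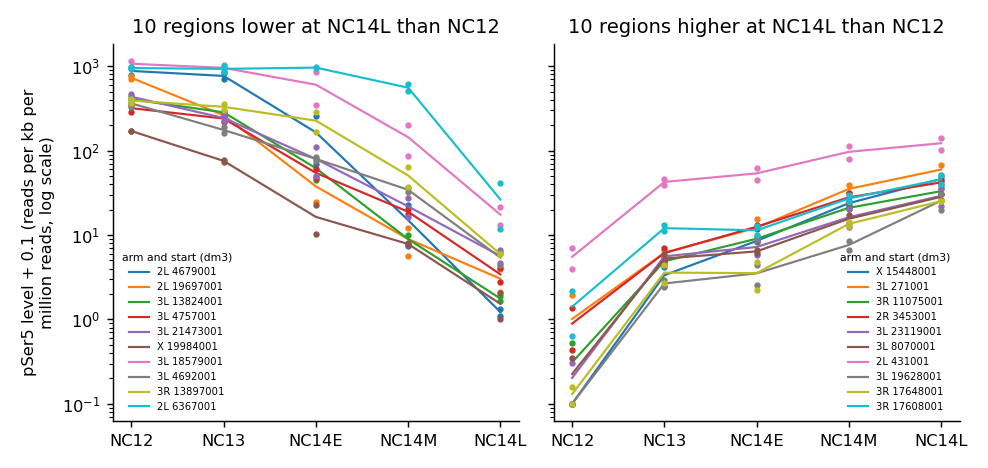
pSer5 level plus 0.1 in reads per kb per M reads (y axis, log scale) at the 5 WT stages (x axis) for the 10 regions with the lowest and the 10 with the highest ratio of NC14L to NC12; points are libraries and lines join the means of 2 libraries. The 2L region starting at 4679001 falls from 881 to 1.12, and the X region starting at 15448001 climbs from 0 to 46.1.

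Signal at summits was sharper in later stages before subtraction of the background, and after it only in some sets of regions. In 2835 regions engaged at NC14L the median log2 ratio of the 400 bp summit to its flanks was 1.67 ± 0.28 (SD, n = 2) at NC12, 1.91 ± 0.06 at NC13, 1.82 ± 0.00 at NC14E, 2.12 ± 0.21 at NC14M and 2.33 ± 0.29 at NC14L; the NC12 libraries were at 1.48 and 1.87 and the NC14L libraries at 2.12 and 2.53. After subtraction of the background it was 2.35 ± 0.12, 2.37 ± 0.08, 2.34 ± 0.09, 2.44 ± 0.24 and 2.56 ± 0.34, so the rise was smaller than the SD at NC14L. In 375 regions engaged at all 5 stages, with background subtracted, the NC12 libraries were at 2.09 and 2.17 and the NC14L libraries at 2.45 and 3.04. In 1855 regions of at least 3 kb, again subtracted, the NC14L libraries at 2.11 and 2.58 lay on either side of the NC12 libraries at 2.19 and 2.24.

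Loss of mei-41 was accompanied by less engaged polymerase at many regions, more often those that WT embryos start to use at NC13. Of 3908 regions, 980 were lower than in WT NC13 and 28 higher, and by size and level alone, with no p, 980 and 29. Among the 1319 regions with an NC13 onset 711 (53.9%) were lower and 2 higher, with a median of -1.04, and among the 738 NC12 regions 207 (28.0%) were lower and 17 higher, with a median of -0.61. Among the deepest falls were those on 2R (start 14424001, end 14428000), from 97.4 ± 4.91 (SD, n = 2) to 8.24 (log2 -3.28), and on 2R (start 8684001, end 8691000), from 54.7 ± 5.99 to 6.49 (log2 -2.74). That last region was among those that rose most from NC12 to NC13 in WT. On 3R (start 27754001, end 27764000) the level fell from 33.7 ± 0.17 to 5.08 (log2 -2.34). Of the 28 regions that rose, 15 were on X. Of these X (start 21772001, end 21773000) went from 8.39 ± 0.84 to 67.5 (log2 2.75) and its neighbour (start 21764001, end 21765000) from 6.79 ± 0.25 to 35.4 (log2 2.09). On X (start 11214001, end 11220000) the level rose from 69.1 ± 6.93 to 262 (log2 1.90), on 3L (start 15058001, end 15073000) from 13.9 ± 1.72 to 78.3 (log2 2.34), and on 4 (start 434001, end 435000) from 1.80 ± 0.88 to 23.6 (log2 2.78).

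The mei-41 change followed the WT step from NC12 to NC13 in reverse across regions. A different WT NC13 library was used in each ratio. Spearman's rho between that step and mei-41 over WT was then -0.40 and -0.37 for the 2 ways round, across 3908 regions that are not independent replicates. WT NC13 enters the ratios with opposite signs, so rho need not be 0 without a change. Given the WT NC13 level, the partial rho was -0.417 and -0.416. For zld, taken in the same way, rho was 0.248 to 0.304. The onset classes use the same WT NC13 libraries as the comparison, so the class difference was repeated with regions matched in level on 1 WT library and compared with the other. NC12 regions then lay above NC13 regions by 0.41 and 0.39 in log2, and by 0.65 and 0.71 after subtraction of background. The median of all regions was -0.74; it shifted by -0.77 after division by background (1959 lower, 8 higher), by 0.33 with shared regions at 0 (408 lower, 41 higher) and by 0.17 with the total over the main arms (652 lower, 35 higher). In a fit of all pSer5 libraries 23 were higher, and in the same fit without WT NC13 replicate 2 the higher count was 14. With 1 mei-41 library, the p behind the calls measures no spread in mei-41. That library had longer reads and another tagged line per the labels, so genotype and kind of library cannot be told apart.

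Loss of zld took polymerase away from the earliest regions and left most later ones in place. Compared with WT NC13, 436 regions were lower and 185 higher, and 317 of the 436 belonged to the 738 regions engaged at NC12 (43.0% of that class, median -1.03). Of the 1319 NC13 regions 95 (7.2%) were lower and 28 higher, with a median of 0.19. Falls reached the background: 2L (start 4679001, end 4691000) held 2.64 ± 0.60 in zld against 768 ± 82.4 in WT (log2 -7.53 with a standard error of 0.14, limma adjusted p 7.3e-06). On 3R (start 8205001, end 8209000) the level was 1.54 ± 0.08 against 248 ± 17.3 (log2 -6.34), on 2L (start 16398001, end 16408000) 0.99 ± 0.39 against 154 ± 2.51 (log2 -5.95), and on X (start 263001, end 266000) 1.05 ± 0.19 against 149 ± 9.62 (log2 -5.86). The 2L region starting at 6367001 kept 11.1 ± 2.68 against 932 ± 94.3 (log2 -6.22). Of the 10 most reduced regions all had an NC12 onset. Matched in level on separate WT libraries, NC12 regions lay below NC13 regions by -0.71 to -0.88 in log2 for the 4 combinations of libraries, and by -0.86 to -1.09 after subtraction of background.

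Many regions that rose in zld had no WT onset. Of the 185, these were 84, a class that by construction holds regions engaged only in a mutant or in 1 replicate. No onset does not mean unused in WT. Of the 544 regions of this class, 144 were called higher and 54 lower at NC14L than at NC12 (limma). The 22 kb region on 3R (start 12634001, end 12656000) rose from 2.02 ± 0.45 to 32.5 ± 3.97 (log2 3.26 with a standard error of 0.16, limma adjusted p 8.1e-05). It lies in a stretch of 3R (start 12541001, end 12751000) in which 9 of 11 regions were higher, and 2 more of the 10 highest followed at 12753001 (37.0 ± 3.49 against 3.42 ± 1.05) and 12773001 (23.6 ± 7.29 against 1.84 ± 0.12). Regions with a WT onset rose too, such as a 31 kb region on 3R (start 2798001, end 2829000) with an NC14L onset, from 4.15 ± 0.23 to 45.2 ± 4.37 (log2 3.04), and 2L (start 5461001, end 5468000), from 14.5 ± 0.05 to 95 ± 9.16 (log2 2.58). On 3L (start 22001, end 23000) no WT NC13 read was found, and the zld level of 21.7 ± 4.45 was at least 180-fold higher against a floor of 3 reads per library. The median bins of the WT NC13 libraries were 1.24 and 1.46, so WT lay below its background there. Why was not tested, and the fold cannot be read as a gain in polymerase alone. In 123 of the 185 regions (66.5%) both zld libraries lay above all 10 WT libraries of any stage.

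The higher calls depended on scaling more than the lower ones, of which 86% to 100% were kept. Total reads gave 29.8% of calls higher; division by background gave 88 higher and 518 lower (14.5%, median shift -0.31), shared regions at 0 gave 91 and 493 (15.6%, shift -0.26), and the total over the main arms gave 371 and 375 (49.7%, shift 0.27). The main arms held 68.4% and 67.9% of the coverage in zld and 85.4% and 84.3% in WT.

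**Figure D3:**
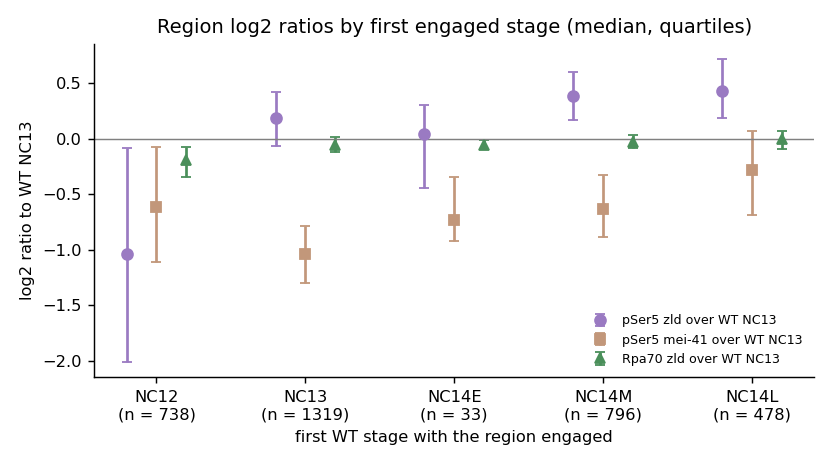
Median log2 ratio to WT NC13 with quartiles as bars (y axis) of pSer5 in zld, pSer5 in mei-41 and Rpa70 in zld, for regions grouped by the first WT stage at which they were engaged (x axis, n regions). In zld the NC12 class has the lowest pSer5 median, -1.03, and in mei-41 the NC13 class does, -1.04.

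Few regions could be called for a difference in Rpa70 between WT and zld, and a strong early region was lower. In all but the top decile of pSer5 level, mean WT Rpa70 was 1.23 to 1.74 median bins. With a pseudocount of about 1 median bin, even a full loss there would give a small ratio, so small ratios do not show that Rpa70 was unchanged. The regions called were 2 higher and 1 lower (limma), with 420 at an unadjusted p under 0.05 and 21 higher and 57 lower by adjusted p alone; few regions reach the level rule, since the signal is shallow. On 2L (start 6367001, end 6379000), among the regions with the most pSer5 at NC13, Rpa70 was 55.2 ± 18.7 (SD, n = 2) in WT and 6.49 in zld, close to the median bin of 5.47 (log2 -2.31). With 1 zld library the p behind this call measures no spread in zld. As for all Rpa70 regions, it rests on a pooled spread, not on that of the WT libraries at this region. Its pSer5 level was 932 in WT and 11.1 in zld. Division by background ended this call at a log2 ratio of -2.30. The 2 higher regions were neighbours on X (start 2684001, end 2688000, and start 2690001, end 2691000), with 126 and 98.4 in zld against 17.8 ± 9.65 and 12.9 ± 7.12 in WT (log2 2.55 for both). The pSer5 libraries were uneven there as well, with a 7.70-fold difference between the 2 WT NC13 libraries and a 6.93-fold one between the 2 zld libraries over the bins of both. With 4 pseudocounts of background 0 regions were called, and without a WT library no test could be made, as no residual degrees of freedom were left.

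**Figure D4:**
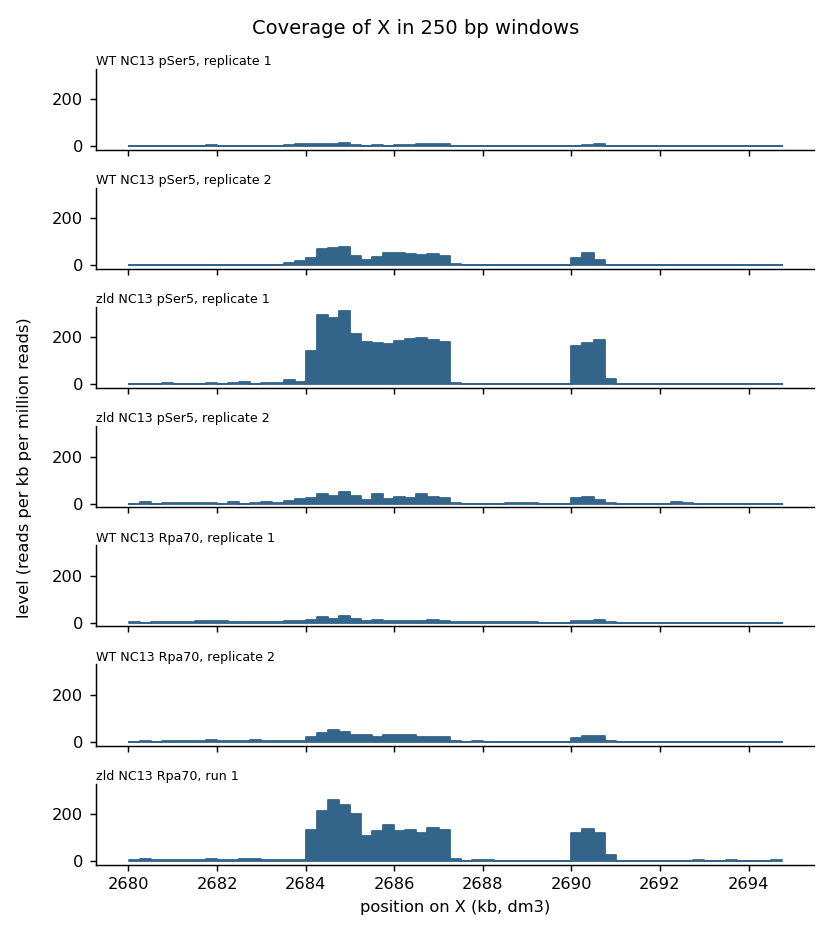
Level in 250 bp windows (y axis, reads per kb per M reads) along X (x axis, dm3) for the libraries named above each panel; the zld Rpa70 panel shows 1 of the 2 runs of its library. The block from 2684001 to 2691000 is high in zld replicate 1 and in zld Rpa70 and low in WT NC13 replicate 1, and the stretch from 2688001 to 2690000 is nearly empty in all panels.

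As a group, regions that lost pSer5 in zld also had less Rpa70. The 436 regions had a mean Rpa70 level of 10.3 ± 1.39 (SD, n = 2) in WT and 6.4 in zld, with a median log2 ratio of -0.28 and 411 of them below 0. In median bins these means were 1.87 and 1.17, and the pseudocount makes the log2 ratio understate such a fall. The medians of 10000 random lists matched on WT Rpa70 level lay between -0.07 and -0.03. At the 400 bp summits the median was -0.72, and with a pseudocount of 4 background medians it was -0.12. Against WT replicate 1 alone it was -0.33 and against WT replicate 2 alone -0.21. The 317 lower regions with an NC12 onset had a median of -0.34 (random lists -0.09 to -0.03). The 185 regions that gained pSer5 had a median of 0.08, above all random lists (-0.08 to -0.01), and 51 of them were below 0.

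Rpa70 was highest where polymerase was densest. Across the 3908 regions Spearman's rho between Rpa70 and pSer5 was 0.53 in WT (0.47 to 0.54 over 4 pairs of libraries) and 0.52 in zld, across regions that are not independent replicates. These regions were chosen for their pSer5 signal, and over all 1 kb bins rho was lower, at 0.423 in WT and 0.288 in zld. In the decile of regions with the least pSer5 the mean Rpa70 level was 6.74 ± 0.25 (SD, n = 2) in WT, and in the decile with the most it was 13.1 ± 2.24. In zld it was 6.11 and 11.5. The median bin was 5.51 in WT, so Rpa70 stood at 2.38 times the background even in the top decile.

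**Figure D5:**
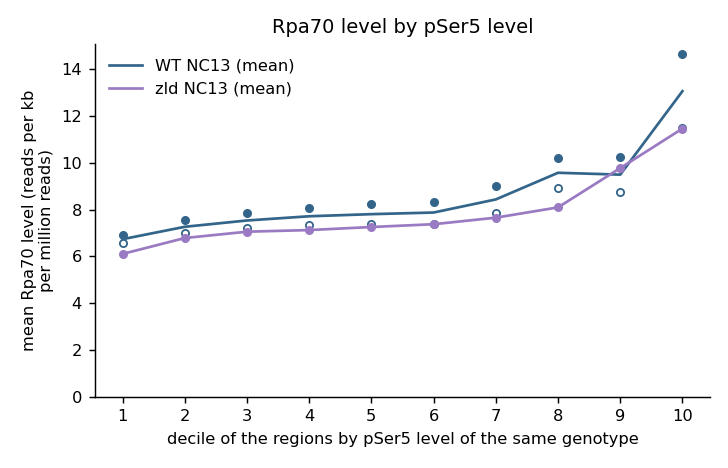
Mean Rpa70 level in reads per kb per M reads (y axis) of the regions in each decile of pSer5 level of the same genotype (x axis); lines are means, filled and open points the WT replicates 1 and 2, and zld has 1 library. WT runs from 6.74 to 13.1 and zld from 6.11 to 11.5.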

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

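Of the tests in this part, only the comparison of mei-41 with the WT step from NC12 to NC13 was set out before its result was seen; the other tests were chosen after.

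Coverage on contigs that gave no regions stood over 1.5 times above the higher WT NC13 library in 4 cases. The unplaced contig Uextra held 27.7% ± 0.15 (SD, n = 2) of the coverage in zld pSer5 and 21.7% in the mei-41 library, against 12% ± 0.57 in WT NC13. The WT NC12 libraries lay between, at 16.8% and 17.0%. The unplaced contig U held 2.56% in mei-41 against 1.41% ± 0.09 in WT NC13, and 1.89% and 1.56% in the WT NC12 libraries. The mitochondrial contig M held 0.293% in mei-41 against 0.088% ± 0.004, 3.26 times the higher of the WT NC13 libraries, but the WT NC12 libraries held 0.299% and 0.4%.

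The lower polymerase levels in mei-41 were weighed first. Lower enrichment as the whole cause would lower early and later regions of equal level alike, but with background subtracted NC12 regions lay above NC13 regions by at least 0.646 in log2, which argues against it. Embryos at an earlier state, closer to WT NC12, would give a negative relation to the WT step from NC12 to NC13. The rank correlation nearer to 0 of the 2 ways round was -0.369 across regions. A delay in the spread of polymerase may thus explain part of the change, though WT NC13 enters both ratios with opposite signs. The longer reads and other tagged line stay open, as 0 WT libraries had that read length. The genotype is thus confounded with the kind of library, and an effect of the checkpoint kinase itself remains an untested hypothesis.

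For the regions higher in zld, weighed next, older embryos in the collection would keep levels within the range of the WT stages, yet in 66.5% of the 185 regions both zld libraries lay above all 10 WT libraries, which argues against age up to NC14L as the whole cause. The share was the same with the 8 libraries of other stages, which played no part in the calls, and 51.4% after division by background (31.4% by over 1.5 times). Regions could however enter through bins engaged only in zld, which raises this share to an extent that was not measured. Age stays open for the rest. Scaling by total reads, with more reads off the main arms in zld, could account for part of the calls: 47.6% of the 185 were still called higher after division by background and 49.2% with shared regions at 0, but all 185 were with the total over the main arms. No value fixes the true scale between the genotypes, so scaling and a gain in zld cannot be told apart for the regions that lost their call. For the 88 regions still called after division by background, a gain in zld is a candidate explanation that was not tested. Of the 185, 20 had an NC12 onset and 28 an NC13 onset, so not all were silent in WT at that stage.

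The third pattern was the block on X (start 2684001, end 2691000), which led the Rpa70 comparison and was chosen with its companions after the values were seen. A difference in copy number between genotypes or stages would leave replicates of a group alike. The block differed over 2 times between libraries in 6 of 7 groups. The pattern was itself picked out by such differences between libraries of a group. That outcome was thus in part fixed beforehand and is no independent test of copy number. Blocks on X (start 2139001, end 2141000) and 3R (start 999001, end 1029000) were found from the first library of each group. In the 7 second libraries the block at 2139001 followed that at 2684001 with a rho of 0.96 and an r of 0.99 on log2 levels (exact permutation p 0.0028 and 0.0006, adjusted over 2 relations 0.0056 and 0.0012), and r was 0.85 without the 2 farthest libraries. The 3R block followed with a rho of 0.75 and an r of 0.62 (exact permutation p 0.066 and 0.13, adjusted 0.066 and 0.13), with an r of 0.95 without the 2 farthest, and 7.29% of 713 other regions had as high a rho, so DNA from a shared outside source in varying amounts is a possible explanation for the X blocks and a weaker one for 3R; an earlier choice of bins over all 16 libraries gave a lowest rho of 0.60.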

How the results depend on the processing

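The settings with the total over the main arms, NC12 left out, all pSer5 libraries in a shared fit, all 1 kb bins, bins engaged in both libraries, both runs counted, and regions engaged at all 5 stages or of at least 3 kb were chosen after seeing the data; the others had been planned. Of the values that answer a comparison, 254 stayed within 1.5 times, or within the spread between libraries, under an alternative. Of the counts of called regions, 64 were lower by over 1.5 times or lost, and 18 were higher by over 1.5 times. The other 51 values moved beyond the spread or by over 1.5 times. The balance of calls turned, with more lower than higher, for NC14M over NC14E and NC14L over NC14M when shared regions were set to 0. It also turned in most fits that left out a library of these stages, but there most calls were lost and the median region hardly moved. Its log2 ratio stayed at 0.427 to 0.458 (0.447 in the main fit) for NC14M over NC14E. For NC14L over NC14M it stayed at 0.203 to 0.234 (0.220 in the main fit). The median region in zld turned from 0.23 to -0.08 after division by background and to -0.04 with shared regions at 0, and at NC14E over NC13 from 0.02 to -0.35 and -0.11. Of the values for single named regions, 142 lost an adjusted p under 0.05 (limma) and 2208 did not. This count leaves aside the size and level parts of the calling rule, so it understates the calls lost. Unless said otherwise, the cause was not tested. With 1 or 2 libraries per group, the spread between libraries limits every comparison, scaling moved the mutant counts further than leaving out a library did, and depth limits regions near the median bin.

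Counts are given as higher and lower. With a pseudocount of 4 background medians, NC13 over NC12 gave 348 and 77, NC14E over NC13 12 and 70, mei-41 288 lower and Rpa70 0 and 0; higher counts were 45 for NC14M over NC14E, 61 for NC14L over NC14M and 82 for zld. The median Rpa70 ratio of regions that lose pSer5 was -0.122. A pseudocount of 0.25 background medians gave 62 higher for NC14L over NC14M, 2 lower for Rpa70 and a median Rpa70 ratio of -0.397. A log2 threshold of 2, which by its construction leaves fewer calls, gave 62 and 17, 1 and 16, 0 and 4, and 11 and 9 for the 4 steps in order, 1495 and 248 for NC14L over NC12, 6 and 37 for mei-41 and 22 and 218 for zld. A level of at least 4 background medians admits more regions and gave 1293 higher for NC13 over NC12, 48 for mei-41, and 4 higher and 5 lower for Rpa70.

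Division by the background median gave 1 higher for NC14E over NC13, 361 and 4 for NC14M over NC14E, 25 and 7 for NC14L over NC14M, 8 and 1959 for mei-41, 88 higher for zld and 0 lower for Rpa70. Shared regions set to 0 gave 13 and 56 for NC14M over NC14E, 42 higher for NC14L over NC14M, 408 lower for mei-41 and 91 higher for zld. The total over the main arms gave 652 lower for mei-41 and 371 higher for zld. Leaving NC12 out of the fit gave 162 higher for NC14L over NC14M, and counting both runs as libraries gave 2 lower for Rpa70.

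Regions built from bins above 5 medians gave 472 higher for NC13 over NC12, 103 for NC14M over NC14E, 574 lower for mei-41 and 2 lower for Rpa70. Those from bins above 20 medians gave 1372 and 69 for NC13 over NC12, 35 higher for NC14L over NC14M, 260 lower for NC14L over NC12, 1530 lower for mei-41, 111 higher for zld and 5 and 0 for Rpa70. Merging bins with no gap changed no such count by over 1.5 times.

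Engaged bins fell with the threshold by construction. Above 4, 5 and 20 medians there were 12393, 9860 and 2511 at NC12, 22662, 19188 and 4854 at NC13, 17751, 14921 and 3630 at NC14E, 6730, 5194 and 1253 in mei-41, and 20871, 16888 and 2390 in zld. For Rpa70 there were 659, 355 and 13 in WT and 382, 212 and 4 in zld, and 70 in both WT Rpa70 libraries. Above 4 and 20 medians there were 26850 and 6953 at NC14M and 30371 and 7125 at NC14L.

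The summit over flank ratio from NC12 to NC14M was 2.35, 2.37, 2.34 and 2.44 with background subtracted. In regions engaged at all 5 stages it was 2.05, 2.23, 2.29, 2.48 and 2.62 from NC12 to NC14L, and in regions of at least 3 kb 1.84 at NC13 and 1.78 at NC14E. The rank correlation across regions between Rpa70 and pSer5 was 0.598 in WT and 0.552 in zld over the 400 bp summit, 0.423 and 0.288 over all 1 kb bins, and 0.453 in zld for engaged regions alone. At the summit the median Rpa70 ratio of regions that lose pSer5 was -0.718.

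Leaving out each library in turn gave these ranges, with a lone library assumed to vary like the other groups and mei-41 taken from the fit of all pSer5 libraries. NC13 over NC12 had 774 to 863 higher and 90 to 126 lower, NC14E over NC13 7 to 33 and 23 to 153, NC14M over NC14E 1 to 230 and 2 to 50, NC14L over NC14M 8 to 162 and 28 to 51, and NC14L over NC12 2365 to 2484 and 336 to 433. For mei-41 there were 14 to 19 higher and 797 to 920 lower, and for zld 164 to 219 and 402 to 433. Engaged bins were 5485 to 10581 at NC12, 11523 to 13362 at NC13, 7943 to 11956 at NC14E, 15506 to 17909 at NC14M, 16378 to 21459 at NC14L, 8727 to 9913 in zld and 71 to 173 for Rpa70 in WT. The summit ratio was 1.48 to 1.87 at NC12, 1.86 to 1.95 at NC13, 1.81 to 1.82 at NC14E, 1.98 to 2.27 at NC14M and 2.12 to 2.53 at NC14L. The rank correlation was 0.479 to 0.539 in WT and 0.508 to 0.509 in zld, and the median Rpa70 ratio -0.333 to -0.212.

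No paired analysis was possible because the replicates recovered from the averaged signal carry no label that matches them between groups, and equal read totals were not taken as one. The alternatives that need an annotation of dm3 were not run: background percentile 95, windows of 1 kb at the start, gene bodies, genes without close neighbours and genes of at least 5 kb.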

Other observations

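The random-list test of Rpa70 was planned; the test of the repeat on 2L was chosen after the result was seen, as were the regions and stretches described here.

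Chromosome 4, the small and largely heterochromatic autosome, held a growing share of the pSer5 signal, in part along with its background. The share of the signal in regions was 0.23% ± 0.014 (SD, n = 2) at NC12, 0.67% ± 0.057 at NC13, 0.84% ± 0.13 at NC14E, 1.2% ± 0.057 at NC14M and 1.26% ± 0.014 at NC14L. In zld at NC13 the share was 1.47% ± 0.064, above every WT stage, and in the mei-41 library it was 0.52%. The median level of its regions relative to chromosomes 2 and 3 was 0.48 at NC12, 0.73 at NC13, 0.82 at NC14E, 0.83 at NC14M, 0.74 at NC14L, 1.21 in zld and 0.93 in mei-41, and that of its bins outside regions 1.15, 1.77, 1.67, 2.21, 2.19, 2.68 and 1.44. These ratios thus did not follow the share at every stage or in mei-41. Of the 65 regions on 4, 7 were called higher and 1 lower in zld, with a median log2 ratio of 0.65, where X had 26 higher and 44 lower of 745, with a median of 0.27. A stretch of 4 (start 943001, end 1136000) held 4 of the higher regions among 14. The X arm changed less for its size, with a share of 11.9% ± 0.57 at NC12 and 13.6% ± 0.078 at NC14L.

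Engagement over time was not a simple gain. Of the 738 regions engaged at NC12, 64.9% were engaged at NC14M and 62.5% at NC14L, against 55.6% at NC14E, and 377 regions were engaged at all 5 stages. Of the regions first engaged at NC13 only 42.3% were engaged at NC14E but 84.1% at NC14M, so many regions dipped below 8 median bins at NC14E, whose median bin was the highest of the WT stages at 1.83. Their level hardly moved, with a median log2 ratio of NC14E to NC13 of 0.03. Engagement needed both libraries, and NC14E replicate 2 had a median bin of 2.22 against 1.49 in replicate 1. In mei-41 40.5% of the NC12 regions and 1.1% of those first engaged at NC13 were engaged, over a median bin of 2.61 against 1.31 in WT NC13, which raises the bar for both. In zld the order was the opposite, with 44.4% and 70.6%.

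The highest zld pSer5 bins lay on 2L (start 21451001, end 21491000), where the mean level was 796 ± 2.29 in zld against 285 ± 11.7 in WT NC13, 461 in mei-41, 425 ± 43.1 at NC12 and 116 ± 23.1 at NC14L. Coverage in this stretch repeated itself with a lag of 5050 bp in every library. A tandem repeat may underlie this spacing, in which case reads are shared between copies and the level is a sum over copies rather than that of any copy. Rpa70 was also high there, at 23.1 ± 3.43 in WT and 42.8 in zld.

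Chance choice of regions was set against the loss of Rpa70 in zld. The median log2 ratio of the 436 regions that lost pSer5, -0.276, lay below all 10000 random lists, the lowest of which had a median of -0.07, which argues against chance choice of regions with this WT Rpa70 level. The lists describe these 3 libraries, and a lower Rpa70 signal where polymerase is lost is consistent with replication stress that follows transcription, a hypothesis that the design leaves untested because zld embryos differ in other ways. A signal that Rpa70 chromatin shares with open or highly transcribed DNA, whatever its source, would give the same result, and the control IgG samples were not analysed here.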
